A study of Mus musculus with 12 samples.

How the data were processed

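RNA was measured in liver and lung of wild-type C57BL/6J mice taken 6 h after sham or CLP surgery, with 3 libraries in each of 4 groups. Per the labels' protocols, total RNA was isolated from tissue kept in a stabilising solution, and libraries were made with a stranded Illumina TruSeq kit and sequenced on a NextSeq500. The deposited values are whole-number counts per gene, not normalized, for 55414 Ensembl mouse gene identifiers, and the counts of 12 libraries stand in 1 table. STAR 2.7.10a, featureCounts, FastQC and DESeq2 and the genome build mm39 are named, per the submitters' processing notes, without a role or order. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Gene symbols were matched by identifier from a reference table of gene names, which gave a symbol for 52081 identifiers and none for 3333. The gene annotation used here was of an older build than mm39, so no positions are given and it served only to find genes whose exons overlap.

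Columns were assigned to libraries by the library names in the labels. The labels give each library an organ, a surgery and a replicate number, but do not say that libraries with the same number came from the same mouse or that each library came from a different mouse. Pairs of replicates were compared by a chi-square test of their counts over genes with at least 20 counts, which gave 5.28 to 37.6 per degree of freedom, so no pair agreed within sampling noise and none was counted as 1 library. Total counts ran from 10559895 to 15854117, and 3 counts in a library came to 0.189 to 0.284 CPM.

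Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes with low counts were removed by edgeR's filter by group (minimum count 10, minimum total 15), libraries were scaled by the trimmed mean of M values, and CLP was set against sham by the quasi-likelihood test with robust dispersion estimates, in 6 libraries for each organ. The difference in response was tested in 1 model of all 12 libraries as the change in lung minus the change in liver. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. CPM are on the scaled library sizes, with exceptions that are on library totals. These are the organ markers, the lung share of liver libraries, and the precursor minus mature neutrophil values. The ratios of Nos2 and Il10 counts and their intervals are also on library totals. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, which is an approximation.

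The 56 gene lists, 31 of pathways and 25 of cell type markers with 1047 entries in all, the tests, the rule for named genes and all alternatives except 2 were fixed before the data were examined. Lists with at least 5 tested members were set against all other genes by camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists. The same test with an estimated correlation, and fry, which asks whether the members of a list move 1 way on balance, were run beside it. The named genes are the 8 largest rises and 8 largest falls per organ among genes past the threshold whose CLP and sham libraries did not overlap and whose mean was at least 3 on the log2 CPM scale, leaving out predicted genes and immunoglobulin and T cell receptor segments. Added to these are, for each list, the 3 members with the lowest p, the 2 with the highest mean and the lowest-p member against the majority, a fixed set of inflammatory and metabolic genes, and the genes with the lowest p in the interaction in each direction and among opposite changes. Some genes that this rule names are not reported here.

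Reads from overlapping genes on opposite strands cannot be told apart unless the counting used strand. Among the genes reported, this applies to Cebpb, Cebpd and Nr1i3, whose exons overlap a protein-coding gene on the other strand, and to Bnc1, Ch25h, Cyp2u1, Gbp2, Ifi47, Il1b, Map4k3, Mt2, Plxna1, Rtkn2, Runx1, Selp, Slc16a5, Tef, Tmem25 and Vcam1, whose exons overlap a non-coding gene or a pseudogene there. Miga2 overlaps a microRNA gene on its own strand. Near-identical genes such as Saa1 and Saa2, and Hba-a1 and Hba-a2, share reads, and their values are uncertain.

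The test was tried on simulated data drawn from the means and library sizes of these libraries, with 100 genes changed by a log2 fold change of 1 and 100 by 2. In liver edgeR recovered 72% and 98% of them over 12075 genes, with 6.59% of its calls false. In lung it recovered 82% and 97% over 15081 genes, with 5.79% false. For the difference between organs it recovered 35% and 72% over 15764 genes, with 6.14% false, and the simulated liver held no response to CLP. The changed genes rose as often as they fell, were drawn without genes of low sham counts, and were far fewer than those called in the data. The rates therefore need not hold for the data or for genes with few counts. The alternatives were DESeq2 1.42.0, limma-voom, other scalings, other low-count filters, a stricter threshold, a fold threshold, non-robust dispersions, the replicate number or the mouse as a block, a fit of all libraries together and each library left out in turn. A subtraction of the reads of the other organ was added after lung transcripts had been seen in liver libraries. It took the share of each library from the median level of marker genes, relative to their own organ, among fixed cell type markers with at least 500 CPM in every library of that organ. The 8 lung markers also had a mean under 2 CPM in the sham liver libraries, a limit that favours a low share in sham, and the 12 liver markers stayed under 1% of their liver level in every lung library. The subtraction in liver was therefore repeated with 10 lung markers chosen by the rule of the liver markers, which was added last and whose shares are the ones given in the results.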

Results

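Transcripts of liver and lung were measured by RNA sequencing in wild-type C57BL/6J mice 6 h after surgery. The mice had undergone either a sham operation or CLP, which in this field stands for cecal ligation and puncture, an operation that releases gut contents into the abdomen and is used as a model of sepsis. Each of the 4 combinations of organ and surgery held 3 libraries, 12 in all, and the series design sets CLP against sham within each organ. Total counts per library ran from 10559895 to 15854117. They ran from 12060375 to 15854117 in sham liver, from 10559895 to 13780640 in CLP liver, from 11946233 to 12931365 in sham lung and from 11298109 to 13590527 in CLP lung. The labels do not state that each library came from a separate mouse, so the p-values measure only the spread between these samples. Marker transcripts matched the organ labels in every library. The plasma protein transcript Alb lay between 46789.8 and 71639 CPM (counts relative to the library total, scaled alike in all libraries) in liver and between 17.1 and 88.0 in lung. The surfactant transcript Sftpc lay between 9949 and 14008 CPM in lung and between 0.301 and 9.38 in liver.

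In the liver, CLP raised inflammatory, interferon-stimulated and neutrophil transcripts and lowered, on balance, transcripts of hepatic nuclear receptors and transcription factors, Kupffer cells and sinusoidal endothelium. These lists were called by camera with a preset correlation, but their adjusted p = 0.109 to 0.334 with an estimated correlation, where camera called 0 lists in liver, against 10 at an unadjusted p under 0.05 and 28 by fry. Among the named genes, the largest rises included Cd14, a receptor for bacterial lipopolysaccharide (ENSMUSG00000051439), which went from 7.78 ± 2.69 to 570.2 ± 191 CPM (SD, n = 3 each), and Serpina3f, a serine protease inhibitor, which went from 3.41 ± 1.14 to 345 ± 42.8 CPM. Nos2, the inducible nitric oxide synthase, had 3 counts over the sham libraries and 709 over the CLP libraries, a ratio of 259 (88.1 to 1257) (95% exact interval for counting error only). The largest falls included Hhex, a homeobox transcription factor of liver (ENSMUSG00000024986), from 61.2 ± 9.91 to 2.16 ± 0.540 CPM, and Tmem25, from 25.1 ± 1.33 to 1.09 ± 0.123 CPM. Of 12392 genes tested, 2647 were higher and 2600 lower after CLP in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, and 1101 and 1219 of these changed at least 2-fold.

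The other genes of the largest rises in liver were Ch25h, cholesterol 25-hydroxylase (log2 fold change 7.43 ± 0.60, standard error), the neutrophil granule gene Ngp (7.42 ± 0.43), Acod1, which makes itaconate (7.10 ± 0.56), Clec4e, a C-type lectin receptor (6.76 ± 0.49), and Olfr56 (6.76 ± 0.52). Olfr56 shares exons with the interferon-induced gene Ifi47 in the reference annotation, so reads of the 2 genes could not be told apart here. The other large falls were G0s2, an inhibitor of lipolysis (-4.70 ± 0.62), the transporter gene Slc16a5 (-4.58 ± 0.25), Paqr7 (-4.32 ± 0.25), Inhba, the inhibin beta A chain (-3.97 ± 0.63), and the clock gene Per3 (-3.81 ± 0.46). Each of these 10 genes had an adjusted p of at most 0.00307 in edgeR with Benjamini-Hochberg adjustment. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 5.50 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0124), but its sham libraries ranged widely, at 278, 55 and 957 counts. Its edgeR adjusted p rose to 0.0727 both without CLP replicate 1 and without CLP replicate 2, to 0.0650 without a low-count filter and, in limma-voom, to 0.106, and its value was -4.32 without sham replicate 3. Leaving out sham replicate 1 moved Acod1 to 9.09, leaving out sham replicate 2 moved Clec4e to 7.41, and leaving out sham replicate 3 moved Ch25h to 8.53 and Inhba to -3.26.

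Of the inflammatory lists in liver, 21 of 22 NF-kB targets and cytokines rose and 0 fell (22 and 0 adjusted over the list alone). For NF-kB targets and cytokines, camera gave an adjusted p of 4.17e-22, and adjusted p = 0.203 with an estimated correlation. Its members included Nfkbia, the feedback inhibitor of NF-kB, at a log2 fold change of 2.33 ± 0.13, Il10 at 6.33 ± 0.67 and Tnf at 4.39 ± 0.65, or 3.68 without CLP replicate 1. Among interferon-stimulated genes 31 of 32 rose and 0 fell (31 and 0 adjusted over the list alone), including the GTPase genes Ifi47 (4.22 ± 0.21) and Gbp2 (5.13 ± 0.27). For interferon-stimulated genes, camera gave an adjusted p of 1.38e-23, and adjusted p = 0.251 with an estimated correlation. Of 19 chemokines, 14 rose, with Cxcl9 at 5.72 ± 0.32 and Ccl5 at 5.07 ± 0.37, and Cxcl12 alone fell, at -1.89 ± 0.18 (15 and 1 adjusted over the list alone). For chemokines, camera gave an adjusted p of 9.44e-10, and adjusted p = 0.109 with an estimated correlation. Negative feedback regulators rose in 15 of 19 cases, including the cytokine signalling inhibitors Socs1 (5.43 ± 0.18) and Socs3 (2.16 ± 0.14) and the phosphatase gene Dusp2 (5.46 ± 0.35), and fell in 2 (16 and 2 adjusted over the list alone). For negative feedback regulators, camera gave an adjusted p of 6.78e-14, and adjusted p = 0.109 with an estimated correlation. Endothelial activation genes rose in 13 of 17 cases and 0 fell, with the adhesion molecule Selp at 4.77 ± 0.20 (13 and 0 adjusted over the list alone). For endothelial activation, camera gave an adjusted p of 1.03e-15, and adjusted p = 0.109 with an estimated correlation. Neutrophil markers rose in all 13 tested cases, with S100a8 from 3.97 ± 0.824 to 52.9 ± 8.22 CPM (13 and 0 adjusted over the list alone), and 9 of 11 monocyte markers rose with 0 falling (9 and 0 adjusted over the list alone). For neutrophils, camera gave an adjusted p of 1.77e-18, and adjusted p = 0.109 with an estimated correlation. For monocytes, camera gave an adjusted p of 2.70e-08, and adjusted p = 0.109 with an estimated correlation.

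The acute phase list rose unevenly in liver. Of 26 members, 17 rose, 1 fell (Orm3) and 8 did not pass the test (18 and 1 adjusted over the list alone). Without sham replicate 3, 11 rose. For acute phase proteins, camera gave an adjusted p of 2.03e-05, and adjusted p = 0.548 with an estimated correlation. The iron carrier Lcn2 rose from 1729 ± 789 to 6389 ± 411 CPM, and Il1rn, the interleukin-1 receptor antagonist, rose by 5.74 on the log2 scale. Orm3 lay at -0.70, with calls that ended without CLP replicate 1 (adjusted p = 0.0982), CLP replicate 2 (0.0822), sham replicate 2 (0.104) or sham replicate 3 (0.0989) in edgeR with Benjamini-Hochberg adjustment. Saa1, a serum amyloid A gene, stood at 6396 ± 689 CPM in sham and 6891 ± 1068 CPM in CLP liver, a difference within the replicate spread (log2 fold change 0.11 ± 0.15); Saa1 and Saa2 are near-identical, so the division of reads between them is uncertain. Glucocorticoid receptor targets rose in 14 of 24 cases and fell in 3 (14 and 4 adjusted over the list alone). For glucocorticoid receptor targets, camera gave an adjusted p of 0.00124, and adjusted p = 0.278 with an estimated correlation. The members went both ways. Cebpd, a transcription factor that inflammatory cytokines also induce, rose by 1.79, while Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, fell by 1.55 on the log2 scale, from 41.1 ± 16.2 to 14.1 ± 0.569 CPM. The values of Fkbp5 and Per1 were -0.02 ± 0.28 and 0.10 ± 0.22, and neither passed the test.

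Regulators of liver gene expression fell more often than they rose. Of 23 hepatic nuclear receptors and transcription factors, 15 fell and 3 rose (3 and 16 adjusted over the list alone). For hepatic nuclear receptors and transcription factors, camera gave an adjusted p of 0.000607, and adjusted p = 0.209 with an estimated correlation. Nr1i3, the constitutive androstane receptor, fell from 120.0 ± 46.6 to 10.3 ± 4.31 CPM, and the fatty acid sensor Ppara fell by 1.27 on the log2 scale, while the inflammation-responsive Cebpb rose by 1.76 and Hnf4a by 0.78. Bile acid synthesis and transport genes fell in 10 of 23 cases, including the canalicular exporter Abcc2 (-1.39 ± 0.22), and rose in 1, Baat (1 and 11 adjusted over the list alone). For bile acid synthesis and transport, camera gave an adjusted p of 0.0248, and adjusted p = 0.622 with an estimated correlation. Drug-metabolising enzymes fell in 7 of 36 cases and 0 rose, with the largest fall named being Cyp2u1 at -3.30 ± 0.28 (0 and 6 adjusted over the list alone), and 17 fell with library totals alone, while 1 rose without CLP replicate 2, without sham replicate 2 or without a low-count filter. Of all 12392 genes tested in liver, 2600 fell and 2647 rose. The share of the list that fell in the main fit was thus no larger than that of all genes, and the list differed in having no rises. For drug-metabolising enzymes, camera gave an adjusted p of 0.0226, and adjusted p = 0.622 with an estimated correlation. Without CLP replicate 2, 2 bile acid genes rose and the calls of both lists ended, at camera adjusted p-values of 0.104 and 0.0713. Liver sinusoidal endothelium markers fell in 10 of 11 cases, with Ehd3 at -1.82 ± 0.19, while Lyve1 rose by 1.71 (1 and 10 adjusted over the list alone). For liver sinusoidal endothelium, camera gave an adjusted p of 0.000661, and adjusted p = 0.334 with an estimated correlation. Kupffer cell markers fell in 6 of 9 cases and 0 rose, with the haemoglobin scavenger receptor Cd163 at -2.26 ± 0.13 and the iron exporter Slc40a1 at -2.57 ± 0.23 (0 and 6 adjusted over the list alone). For Kupffer cells, camera gave an adjusted p of 0.000768, and adjusted p = 0.227 with an estimated correlation. The hepatocyte list was not called, with 4 of 15 members higher and 3 lower (4 and 3 adjusted over the list alone), or 3 higher and 6 lower with library totals alone and 3 and 4 with upper-quartile scaling. For hepatocytes, camera gave an adjusted p of 0.894, and adjusted p = 0.981 with an estimated correlation. Markers of alveolar type 2 cells, a lung cell type, were higher in 7 of 11 cases with 0 lower (7 and 0 adjusted over the list alone), or 7 and 1 with library totals alone. For alveolar type 2 cells, camera gave an adjusted p of 0.0167, and adjusted p = 0.209 with an estimated correlation. Over 10 markers of lung epithelium, chosen by a rule that treats CLP and sham liver alike, the median was 0.0827 to 0.125% of the lung level in the CLP liver libraries and 0.0163 to 0.0324% in sham. The call ended after this lung share of the reads was subtracted (camera adjusted p = 0.534), but 6 of the 10 markers are members of the list. Scaling by library totals alone shifted the median gene by -0.20 on the log2 scale and gave 1689 higher and 3796 lower genes, and upper-quartile scaling shifted it by -0.09 and gave 2122 and 3144. Camera called 21 of 46 lists in liver (15 up, 6 down). Other divisions of the same 6 libraries into 3 and 3 gave up to 24 calls, but these keep part of the CLP response.

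**Figure D1:**
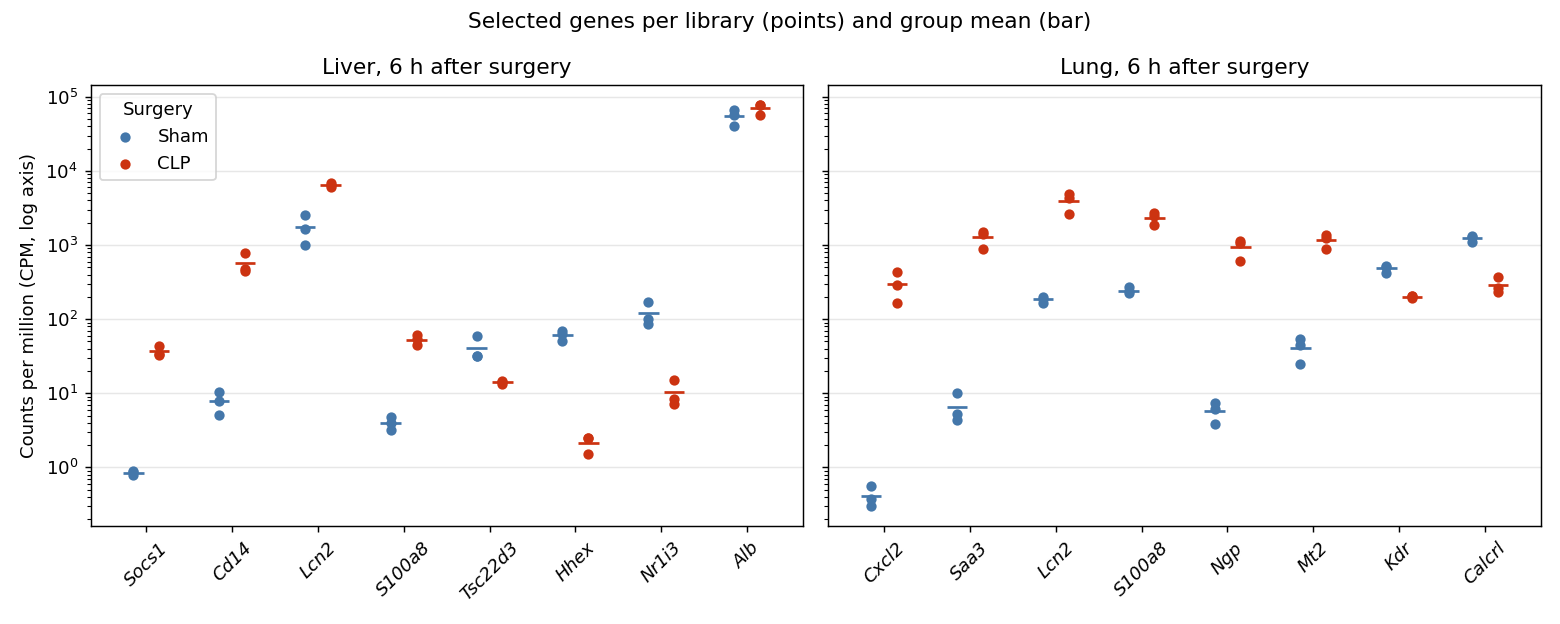
CPM (log axis) of 8 genes in liver (left) and 8 in lung (right), 6 h after sham (blue) or CLP (red) surgery; each point is 1 library and each bar the mean of 3. For liver Cd14 all 3 CLP libraries lie above all 3 sham libraries (means 570.2 and 7.78), and for Hhex all lie below; liver Alb overlaps between the groups.

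In the lung, CLP raised chemokines and cytokines, neutrophil, monocyte, T cell and NK cell markers and NRF2 targets and metal response genes, and lowered transcripts of alveolar type 1 cells and, on balance, of capillary endothelium and endothelial identity and junctions. Camera called these lists with a preset correlation, but their adjusted p = 0.200 to 0.562 with an estimated correlation, where it called 0 lists in lung, against 7 at an unadjusted p under 0.05 and 33 by fry. The neutrophil attractant Cxcl2 (ENSMUSG00000058427) went from 0.414 ± 0.139 to 296 ± 132 CPM (SD, n = 3 each), and the serum amyloid gene Saa3 from 6.63 ± 3.09 to 1281 ± 335 CPM. Il10, an anti-inflammatory cytokine, had 3 counts over the sham and 2101 over the CLP libraries, a ratio of 702 (240.0 to 3409) (95% exact interval for counting error only). Its CLP libraries held 716, 1309 and 76 counts, and its adjusted p was 0.00992 in edgeR with Benjamini-Hochberg adjustment and 0.0683 in limma-voom. The largest falls included Glp1r, the glucagon-like peptide 1 receptor (ENSMUSG00000024027), from 187 ± 48.5 to 8.72 ± 4.11 CPM, and Kank4, from 30.4 ± 3.25 to 2.66 ± 1.21 CPM. Of 15441 genes tested, 3698 were higher and 3850 lower after CLP (edgeR, Benjamini-Hochberg adjusted p below 0.05), and 1454 and 912 of these changed at least 2-fold.

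Other large rises in lung were the chemokines Ccl3 (log2 fold change 9.28 ± 1.11, standard error), Cxcl3 (7.95 ± 0.74) and Ccl4 (7.75 ± 1.29), the antimicrobial peptide gene Camp (8.79 ± 0.35) and Tnf (7.43 ± 1.06). Other large falls were Pcdhac2 (-3.50 ± 0.40), the signalling ligand Wnt3a (-3.39 ± 0.27), Ankrd63 (-3.34 ± 0.32), Prrt4 (-3.17 ± 0.38), Sh3rf2 (-2.75 ± 0.20) and Smad9, a transducer of bone morphogenetic protein signals (-2.71 ± 0.33). Each of these 11 genes had an adjusted p of at most 0.00573 in edgeR with Benjamini-Hochberg adjustment. Without CLP replicate 1 the values of Ccl3, Ccl4, Cxcl3 and Tnf were 8.65, 6.80, 7.33 and 6.74, without CLP replicate 3 those of Pcdhac2 and Prrt4 were -4.16 and -3.87, and without sham replicate 1 that of Ccl3 was 9.87. Pcdhac2 shares exons with other protocadherin alpha genes, so its reads could not be assigned to it alone.

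Markers of several immune cell types rose in lung. All 16 neutrophil markers rose, with S100a8 from 244 ± 23.4 to 2335 ± 446 CPM and Il1r2, a decoy interleukin-1 receptor, at a log2 fold change of 3.48 ± 0.14 (16 and 0 adjusted over the list alone). For neutrophils, camera gave an adjusted p of 8.98e-27, and adjusted p = 0.200 with an estimated correlation. All 7 tested precursor markers also rose (7 and 0 adjusted over the list alone), and the granule gene Ngp went from 5.78 ± 1.82 to 932 ± 281 CPM. For neutrophil precursors, camera gave an adjusted p of 7.74e-11, and adjusted p = 0.306 with an estimated correlation. All 11 monocyte markers rose, with Plac8 at 3.27 ± 0.11 and the Fc receptor gene Fcgr1 at 3.09 ± 0.15 (11 and 0 adjusted over the list alone). For monocytes, camera gave an adjusted p of 8.98e-27, and adjusted p = 0.200 with an estimated correlation. T cell markers rose in 11 of 17 cases, including Cd3d, a chain of the T cell receptor complex (1.92 ± 0.25), and 0 fell (11 and 0 adjusted over the list alone). For T cells, camera gave an adjusted p of 0.000364, and adjusted p = 0.562 with an estimated correlation. NK cell markers rose in 8 of 13 cases, including granzyme B, Gzmb (3.88 ± 0.27), and 0 fell (8 and 0 adjusted over the list alone). For NK cells, camera gave an adjusted p of 2.72e-05, and adjusted p = 0.384 with an estimated correlation. B cell markers rose in 6 of 14 cases and 0 fell (6 and 0 adjusted over the list alone). For B cells, camera gave an adjusted p of 0.0249, and adjusted p = 0.740 with an estimated correlation. That call ended without CLP replicate 1 (0.0904), CLP replicate 3 (0.285) or sham replicate 2 (0.0941, with 1 lower). Tissue macrophage markers were higher in 7 of 12 cases and lower in 2 (7 and 2 adjusted over the list alone), with 4 higher without sham replicate 2, and also with library totals alone or upper-quartile scaling. For tissue macrophages, camera gave an adjusted p of 0.0950, and adjusted p = 0.384 with an estimated correlation. The list was called without CLP replicate 2 (0.0402) and without a low-count filter (0.0264). Alveolar macrophage markers were higher in 3 of 14 cases and lower in 3 (3 and 3 adjusted over the list alone), or 1 and 4 with library totals alone or upper-quartile scaling, and 1 was higher without sham replicate 3. For alveolar macrophages, camera gave an adjusted p of 0.966, and adjusted p = 0.978 with an estimated correlation. Dendritic cell markers were higher in 3 of 12 cases and lower in 3 (3 and 3 adjusted over the list alone), with 1 lower without sham replicate 1 or sham replicate 3. For dendritic cells, camera gave an adjusted p of 0.925, and adjusted p = 0.949 with an estimated correlation. Of the tested cell cycle genes, 18 of 24 rose and 0 fell, with cyclin B2, Ccnb2, at 1.98 ± 0.23 (18 and 0 adjusted over the list alone). For cell cycle, camera gave an adjusted p of 9.15e-05, and adjusted p = 0.484 with an estimated correlation.

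Chemokines rose in 19 of 21 cases in lung and fell in 2, with Cxcl1 at 6.45 ± 0.90, or 5.65 without CLP replicate 1, and Cxcl12 at -1.17 ± 0.21 (19 and 2 adjusted over the list alone). For chemokines, camera gave an adjusted p of 1.66e-13, and adjusted p = 0.306 with an estimated correlation. NF-kB targets and cytokines rose in 23 of 25 cases and 0 fell, with Il1b at 3.16 ± 0.12 and Nos2 at 3.32 ± 0.26 (23 and 0 adjusted over the list alone). For NF-kB targets and cytokines, camera gave an adjusted p of 2.05e-16, and adjusted p = 0.384 with an estimated correlation. Interferon-stimulated genes rose in 31 of 32 cases and 0 fell, with the nucleic acid sensor Zbp1 at 3.48 ± 0.15 (31 and 0 adjusted over the list alone). For interferon-stimulated genes, camera gave an adjusted p of 1.10e-21, and adjusted p = 0.384 with an estimated correlation. Endothelial activation genes rose in 14 of 17 cases, with the adhesion molecule Vcam1 at 0.92 ± 0.09, and fell in 1, Vwf, von Willebrand factor, at -0.66 ± 0.13 (14 and 1 adjusted over the list alone). Without CLP replicate 2, 2 fell. For endothelial activation, camera gave an adjusted p of 1.49e-07, and adjusted p = 0.384 with an estimated correlation. Of 21 NRF2 targets and metal response genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone). For NRF2 targets and metal response, camera gave an adjusted p of 5.08e-12, and adjusted p = 0.384 with an estimated correlation. Mt2, a metallothionein that binds zinc, went from 41.3 ± 14.8 to 1166 ± 245 CPM, and the zinc importer Slc39a14 rose by 3.50 on the log2 scale. Acute phase genes rose in 15 of 23 cases and 0 fell, with Lcn2 from 185 ± 18.9 to 3955 ± 1161 CPM and Saa1 from 3.49 ± 4.25 to 57.5 ± 15.4 CPM (15 and 0 adjusted over the list alone). For acute phase proteins, camera gave an adjusted p of 1.68e-09, and adjusted p = 0.384 with an estimated correlation. The liver transcript Alb reached 88.0 CPM in lung sham replicate 1, the highest value among the lung libraries, and that library held 103 of the 131 sham counts of Saa1, whose log2 fold change was 4.07 with it and 5.76 without it. Glucocorticoid receptor targets rose in 13 of 22 cases and fell in 2 (13 and 2 adjusted over the list alone), and the values of Tsc22d3 and Per1 were 0.12 ± 0.12 and 0.12 ± 0.15. For glucocorticoid receptor targets, camera gave an adjusted p of 7.54e-08, and adjusted p = 0.200 with an estimated correlation. With any 1 library left out, at most 1 fell. Fkbp5 rose by 1.62 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0116), a call that ended without CLP replicate 3 (0.0620) and without a low-count filter (0.0864).

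Alveolar type 1 cell markers fell in 9 of 13 cases and 0 rose, with Rtkn2 at -2.21 ± 0.24 and Akap5 at -2.11 ± 0.20 (0 and 10 adjusted over the list alone). For alveolar type 1 cells, camera gave an adjusted p of 0.000727, and adjusted p = 0.562 with an estimated correlation. Of 14 alveolar type 2 cell markers, 2 were higher and 3 were lower (1 and 3 adjusted over the list alone), or 0 and 4 with library totals alone or upper-quartile scaling, and the value of Sftpc was -0.22 ± 0.12. It passed the edgeR test under those scalings, at -0.33 under each (Benjamini-Hochberg adjusted p below 0.05). The number of type 2 markers that were higher was 1 without CLP replicate 1, sham replicate 1, sham replicate 3 or a low-count filter, and 0 without sham replicate 2. For alveolar type 2 cells, camera gave an adjusted p of 0.740, and adjusted p = 0.949 with an estimated correlation. Lung capillary endothelium markers fell in 7 of 12 cases and rose in 2 (2 and 7 adjusted over the list alone). For lung capillary endothelium, camera gave an adjusted p of 0.00127, and adjusted p = 0.384 with an estimated correlation. The receptor gene Calcrl fell from 1228 ± 117 to 287 ± 68.9 CPM and the vascular endothelial growth factor receptor Kdr from 489 ± 55.5 to 201 ± 7.89 CPM. Endothelial identity and junction genes fell in 14 of 26 cases and rose in 5, with the transcription factor Sox18 at -1.24 ± 0.10 and the tight junction gene Cldn5 at 0.88 ± 0.13 (6 and 16 adjusted over the list alone), and 3 rose and 16 fell with library totals alone or upper-quartile scaling, while 3 rose without CLP replicate 1 or sham replicate 2. For endothelial identity and junctions, camera gave an adjusted p of 0.00918, and adjusted p = 0.384 with an estimated correlation. Mesothelium markers fell in 6 of 10 cases and 0 rose, with Bnc1 at -2.09 ± 0.37 (0 and 6 adjusted over the list alone). For mesothelium, camera gave an adjusted p of 0.0243, and adjusted p = 0.562 with an estimated correlation. Of 11 cardiac muscle markers 0 passed the edgeR test, and 0 had an unadjusted p under 0.05 (0 and 0 adjusted over the list alone), with a median log2 fold change of -0.48, but without CLP replicate 2 the list was called (camera adjusted p = 0.00651) and 5 were lower. For cardiac muscle, camera gave an adjusted p of 0.399, and adjusted p = 0.949 with an estimated correlation. Of 9 fat tissue markers, 1 was lower, Pck1, and 0 were higher (0 and 0 adjusted over the list alone), with 4 lower without CLP replicate 2, 2 lower with library totals alone, upper-quartile scaling or no low-count filter, and 0 without any other 1 library except sham replicate 1. The call of Pck1 also ended after the reads of the other organ were subtracted (log2 fold change -1.30, edgeR adjusted p = 0.265). For fat tissue, camera gave an adjusted p of 0.857, and adjusted p = 0.949 with an estimated correlation. The fat marker Car3 lay at 0.31 with CLP replicate 2 and at -1.41 without it. Library totals alone shifted the median gene by -0.10 on the log2 scale and gave 2977 higher and 4847 lower genes, and upper-quartile scaling shifted it by -0.11 and gave 2929 and 4946. Camera called 27 of 54 lists in lung (22 up, 5 down). Other divisions of these 6 libraries into 3 and 3 gave up to 28 calls, but these keep part of the CLP response.

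**Figure D2:**
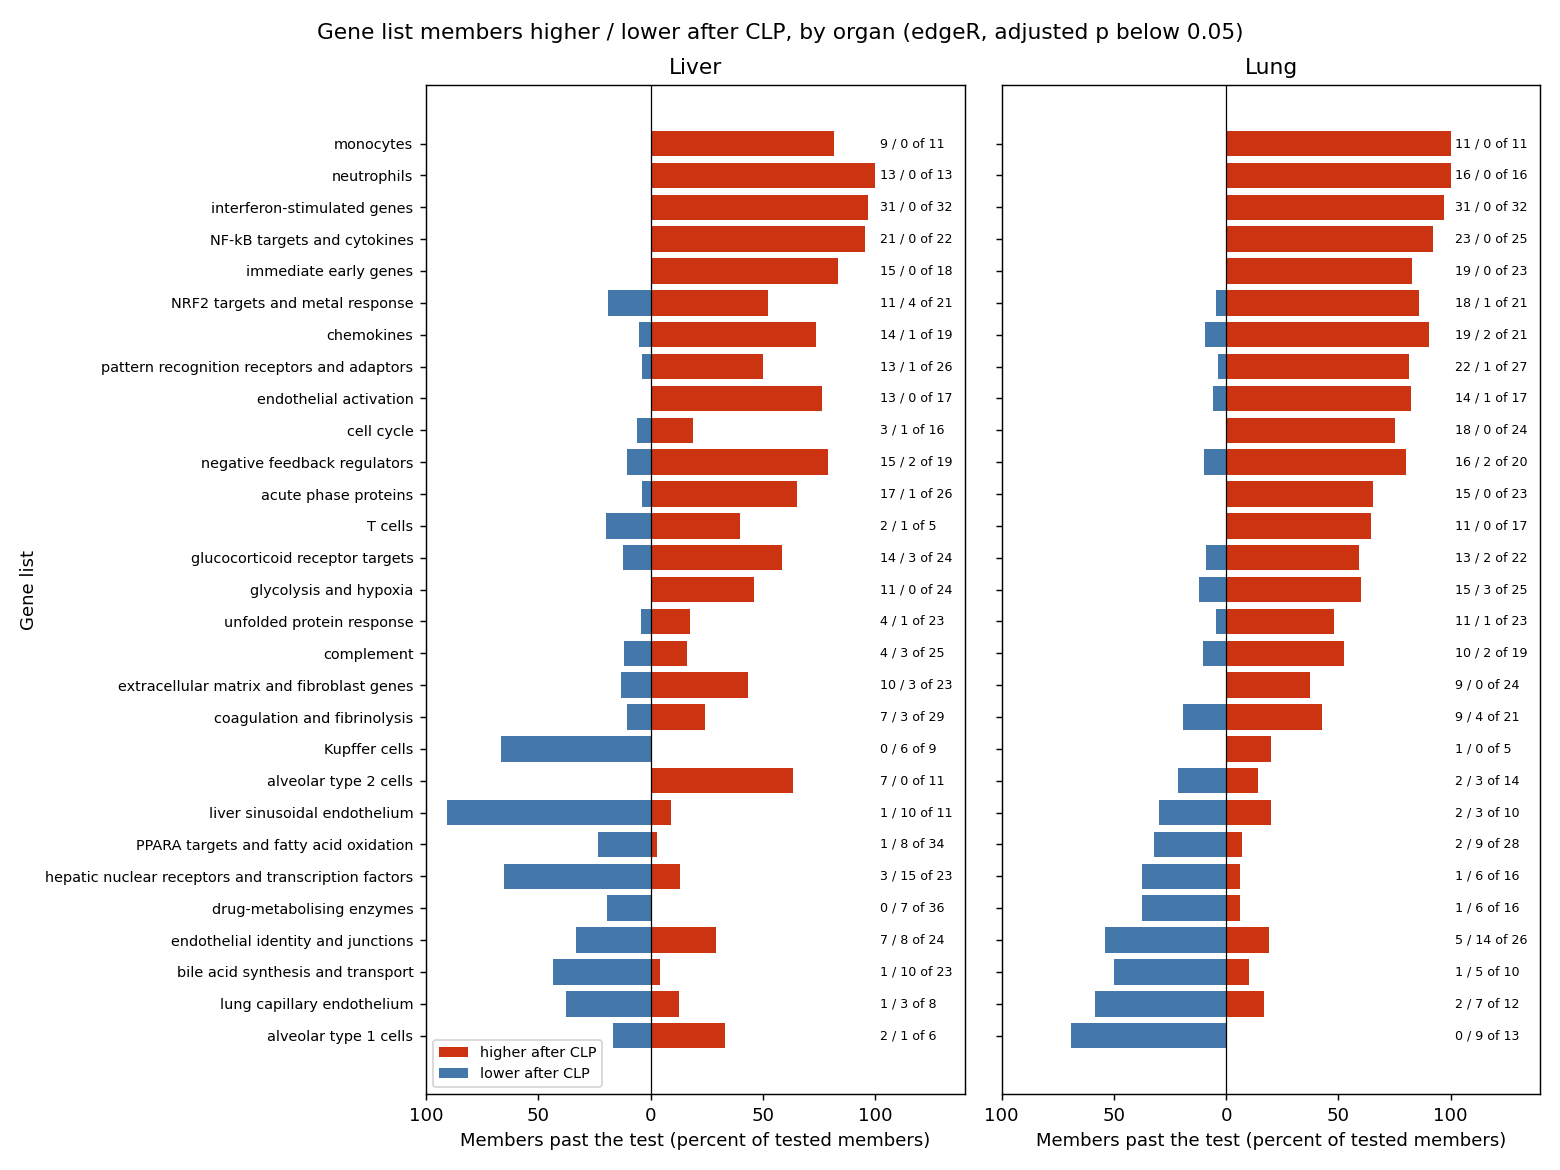
Bars give the percent of tested members of 29 gene lists that passed the edgeR test as higher (red, to the right) or lower (blue, to the left) after CLP in liver and lung; numbers at the right of each panel are members higher / lower of those tested. Neutrophil markers rose in 13 of 13 cases in liver and 16 of 16 in lung, and Kupffer cell markers fell in 6 of 9 in liver.

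Across organs, many of the genes that responded to CLP did so in both and in the same direction. Of 11781 genes tested in both, 3181 passed the edgeR test in each organ, where independent lists of these sizes would share 2582. Among them 1576 rose in both (682 for independent lists), 1276 fell in both (610) and 329 changed in opposite directions, of which 171 rose in liver and fell in lung (661) and 158 fell in liver and rose in lung (629). Fisher's exact test, two-sided, gave an odds ratio of 2.34 and p = 1.23e-111 for being past the threshold in both organs, as a description only, since genes are not independent replicates. Across genes, the log2 fold changes of the organs correlated with Pearson's r = 0.621 and Spearman's rho = 0.558. With library totals alone, 3392 genes passed in both organs, 1020 of them higher and 2046 lower in both.

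**Figure D3:**
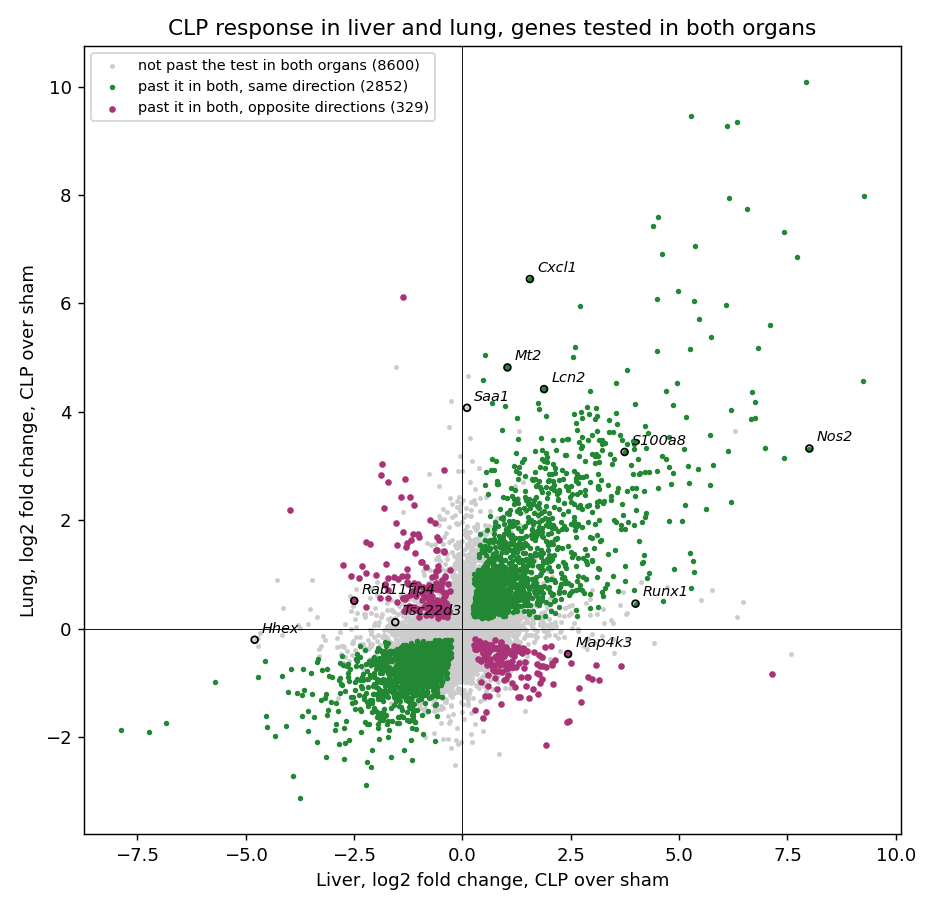
Log2 fold change of CLP over sham in liver (x axis) and lung (y axis) for the 11781 genes tested in both organs; green points passed the edgeR test in both organs in the same direction (2852) and purple points in opposite directions (329). Map4k3 lies at the lower right and Rab11fip4 at the upper left.

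The response itself differed between lung and liver for 2856 of 16111 genes in a model of all 12 libraries (edgeR interaction, Benjamini-Hochberg adjusted p below 0.05), 1432 with a higher and 1424 with a lower log2 fold change in lung. Hhex, Rab11fip4, Miga2 and Tgfbi were among the genes with the lowest p-values for a higher response in lung, and Map4k3, Ppm1l, Runx1 and Plxna1 among those for a lower response. The kinase gene Map4k3 (ENSMUSG00000024242) rose in liver from 36.9 ± 2.92 to 201 ± 39.3 CPM and fell in lung from 95.5 ± 3.65 to 67.9 ± 2.03 CPM, a difference of -2.94 ± 0.17 on the log2 scale. The phosphatase gene Ppm1l (-2.72 ± 0.17) likewise rose in liver and fell in lung. Rab11fip4 fell in liver from 23.1 ± 2.64 to 4.11 ± 0.672 CPM and rose in lung from 10.0 ± 0.294 to 14.1 ± 0.912 CPM (2.98 ± 0.20). Hhex differed by 4.56 ± 0.24, with a lung value of -0.20 ± 0.12, and Runx1, a blood cell transcription factor, by -3.57 ± 0.23, going from 1.80 ± 0.711 to 28.5 ± 2.75 CPM in liver and from 33.1 ± 2.07 to 44.8 ± 0.497 CPM in lung. The differences of Miga2, Tgfbi and Plxna1 were 1.97 ± 0.14, 1.96 ± 0.14 and -1.95 ± 0.13, and the adjusted p of these 8 genes was at most 4.17e-06 in edgeR with Benjamini-Hochberg adjustment.

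Among genes fixed before the data were examined, Nos2, Cxcl1, Saa1, Lcn2, Tsc22d3, Socs3 and Sftpc differed in response between the organs, each with an adjusted p of at most 0.00580 in edgeR with Benjamini-Hochberg adjustment. Nos2 rose more in liver, where its sham libraries held 3 counts in all, so no size is given. Cxcl1 (4.85 ± 0.92), Saa1 (3.93 ± 0.76), Lcn2 (2.51 ± 0.44), Tsc22d3 (1.64 ± 0.30) and Socs3 (1.10 ± 0.22) had the higher response in lung, by the lung minus liver log2 differences given. The difference of the lung epithelial transcript Sftpc, -3.09 ± 0.49, set a lung value of -0.22 ± 0.12 against a liver value of 2.84 ± 0.48 (3.49 without liver sham replicate 1), where it stood at 0.0576% of its lung level in CLP and 0.00934% in sham. Fkbp5 also passed (1.61 ± 0.51, edgeR adjusted p = 0.0488), but its call ended without any 1 library other than liver CLP replicate 3, liver sham replicate 3, lung sham replicate 2 and lung sham replicate 3 (up to 0.104), and ended at 0.178 without a low-count filter, 0.0522 with relative log expression scaling and 0.0515 with upper-quartile scaling. Without lung CLP replicate 1 the difference of Cxcl1 was 4.04, and without lung sham replicate 1 that of Saa1 was 5.62. The neutrophil marker S100a8 did not pass this test (-0.51 ± 0.26). Of 8 tested neutrophil precursor markers, 3 had a higher response in lung and 0 a lower one (3 and 0 adjusted over the list alone), with a camera adjusted p of 0.188 and adjusted p = 0.920 with an estimated correlation. These were Cebpe, Elane and Prtn3, named after their values were seen, whose counts over the liver libraries were 89, 9 and 89 in sham and 29, 0 and 21 in CLP. NRF2 targets and metal response genes had a higher response in lung for 10 of 22 members and a lower one for 0 (12 and 0 adjusted over the list alone), with Mt1 at 3.45 ± 0.30 and Mt2 at 3.75 ± 0.37. For the response of NRF2 targets and metal response, camera gave an adjusted p of 7.53e-09, and adjusted p = 0.429 with an estimated correlation. Liver sinusoidal endothelium markers were higher in response in lung for 4 of 11 and lower for 0 (6 and 0 adjusted over the list alone), Kupffer cell markers for 3 of 9 and lower for 0 (4 and 0 adjusted over the list alone), and tissue macrophage markers for 6 of 12 and lower for 0 (6 and 0 adjusted over the list alone). For the response of liver sinusoidal endothelium, camera gave an adjusted p of 0.000472, and adjusted p = 0.429 with an estimated correlation. For the response of Kupffer cells, camera gave an adjusted p of 0.00126, and adjusted p = 0.429 with an estimated correlation. For the response of tissue macrophages, camera gave an adjusted p of 0.000627, and adjusted p = 0.600 with an estimated correlation. Endothelial activation genes had a lower response in lung for 7 of 17 members, including Procr, the endothelial protein C receptor (-3.82 ± 0.67, or -4.48 without liver sham replicate 2), and a higher one for 2 (2 and 8 adjusted over the list alone). Without liver sham replicate 3, 4 had a lower response, and without a low-count filter 3. The number with a higher response was 1 without any 1 library other than liver CLP replicate 2, liver sham replicate 2, liver sham replicate 3 and lung CLP replicate 3. For the response of endothelial activation, camera gave an adjusted p of 0.0158, and adjusted p = 0.920 with an estimated correlation. Library totals alone shifted the median difference by 0.12 and gave 1861 higher and 965 lower genes. Camera called 9 of 54 lists (5 up, 4 down), a number that 92 of 100 divisions of the libraries within organs reached or passed. The divisions other than the real one keep all or part of the CLP response of each organ.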

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

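The tests of the difference between organs and the divisions of the libraries were fixed before the data were examined, and the tests that weigh the pair of patterns in this part were chosen after the result was seen. The response to CLP differed between lung and liver for 2856 genes and 9 lists by the interaction test. Among the genes with the lowest p for a higher log2 fold change in lung were Hhex (4.56), Rab11fip4 (2.98), Miga2 (1.97) and Tgfbi (1.96). Among those for a lower one were Map4k3 (-2.94), Ppm1l (-2.72), Runx1 (-3.57) and Plxna1 (-1.95).

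Of the 9 lists, 5 had a higher response in lung by camera. They were NRF2 targets and metal response (adjusted p = 7.53e-09), liver sinusoidal endothelium (0.000472), tissue macrophages (0.000627), Kupffer cells (0.00126) and acute phase proteins (0.0488). The 4 with a lower response were alveolar type 2 cells (3.24e-07), endothelial activation (0.0158), alveolar type 1 cells (0.0189) and erythroid cells (0.0328). With an estimated correlation 0 lists passed, 4 had an unadjusted camera p under 0.05, and fry called 7. The acute phase call ended without any 1 library other than liver sham replicate 3, lung CLP replicate 3 and lung sham replicate 1, with adjusted p-values of up to 0.180, and at 0.0713 with library totals alone. The call of alveolar type 1 cells ended without liver CLP replicate 3 (0.0711), and that of erythroid cells without liver CLP replicate 1 (0.0563), liver sham replicate 1 (0.0793), liver sham replicate 2 (0.0529), lung CLP replicate 3 (0.0742) or lung sham replicate 3 (0.0643).

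Other divisions of the libraries were tried. For the interaction, 100 of 200 divisions within organs were drawn, and 2 of them gave at least 2856 genes, the real one included. Mixing CLP and sham in an organ leaves part of its response in the contrast and moves the rest into the spread within groups. These divisions therefore cannot tell whether responses present in both organs differ by chance. At an unadjusted p under 0.05, 5 of the 100 gave at least the 4923 genes found, the real one included. The 4 others all keep CLP apart from sham in at least 1 organ and so hold its response. That count therefore cannot decide on chance. Genes were called in 17 other divisions, all of which keep CLP apart from sham in at least 1 organ, so that their contrast holds the response of that organ and points to that structure of the samples. The highest gave 7956 genes, in the division that exchanges CLP and sham in lung alone and so adds the responses of both organs, and the next gave 2531. The 82 divisions that mix CLP and sham in both organs gave 0 genes by edgeR, with at most 604 at an unadjusted p under 0.05. The spread that mixing adds also lowers these numbers, so they are not counts free of a response. For the lists, 92 of the 100 gave at least the 9 found, with up to 34. The other divisions keep all or part of the response of each organ, so they do not measure chance alone. Chance can therefore not be excluded for the number of lists, nor does this count speak for it. For genes past the test in both organs, 1 of 100 pairs of divisions, the real one, gave 3181, and the highest other gave 0. Every other division of either organ alone called 0 genes, which fixes that outcome, so the pairs decide nothing beyond the divisions of each organ. In each organ alone the 10 divisions are too few for a share under 0.05. All but the real one mix CLP and sham, which adds to the spread within groups and lowers the number of genes called. Liver gave 5247 genes and lung 7548 by edgeR in 1 of 10 divisions, the real one, and the highest other gave 0, with at most 202 and 265 genes at an unadjusted p under 0.05; no other tool was run on these divisions. For the lists, 3 of 10 divisions in liver gave at least the 21 found, with up to 24, and 2 of 10 in lung gave at least 27, with up to 28. Since the other divisions keep part of the CLP response, their list calls do not measure chance alone.

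Alveolar type 2 markers, whose response was lower in lung, were higher in CLP than in sham liver for 7 of 11, while the type 1 list was not called in liver (2 of 6 higher, 1 lower, camera adjusted p = 0.847) and fell in lung itself (9 of 13). Of 10 markers of lung epithelium chosen alike over CLP and sham liver libraries, 9 were higher in CLP, by 0.0482 to 0.151% of their lung level, while Emp2, named after its value was seen, lay at -0.0352% (standard error 0.0736), so that a single share of lung RNA or reads carried over and liver cells that turn on each gene at its own level cannot be told apart, since the error of that marker allows either. The median log2 ratio of the 10 markers, 1.72 (SD 1.08), exceeds the largest shift between scalings, 0.20, by more than that SD, which argues against scaling. Carry-over from lung may account for the type 2 call in liver, while the number of genes called in liver barely depends on it, since subtracting the lung share, at most 0.125% in a liver library, left 5203 genes called. What could make such a carry-over larger in CLP than in sham liver libraries was not tested, as the labels give no order or batch of dissection or sequencing.

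The falls of Kupffer cell and sinusoidal endothelial markers in liver, 16 of 20 lower with Lyve1 the 1 that rose, set these lists apart between organs. Their median log2 fold change was -1.02, and that of the hepatocyte list was -0.026 (SD 0.51), with 3 higher and 6 lower of 15 under library totals alone, which shift the median gene by -0.20, and this argues against dilution by incoming cells or induced transcripts. Under 3 other scalings the median nearest to 0 was -1.02, which argues against scaling. The members moved by different sizes, with a chi-square of 24.4 per degree of freedom over their errors. That value pools both cell types against 1 common size, so unequal loss of each could also raise it. It cannot decide whether loss of these cells is the only cause. Loss of these cells, lower transcript levels within them, or both, may account for the pattern and were not tested.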

How the results depend on the processing

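All of these alternatives were fixed before the data were examined, except the 2 subtractions of the reads of the other organ. Of 1153 results for named genes, alternatives kept the side of the threshold in 20911 cases, lost the call in 655 and gained 1 in 388. In 3 cases the sign reversed with a call in either fit. Sign changes between values that missed the threshold in both fits stand among the 20911. The 3 were Fgb in lung without lung sham replicate 1 (1.47, with -0.77 to 1.47 over libraries left out), Car3 in lung without lung CLP replicate 2 (-1.41, range -1.41 to 0.77) and Car3 in the difference between organs without lung CLP replicate 2 (-1.73, range -1.73 to 0.47), and the cause was not tested. Of the single lists, 2320 cases stayed on their side of the threshold, 107 lost the call and 45 gained 1. The counts of genes in liver, in lung, in their difference and in both organs were 4911, 6986, 3401 and 2912 with DESeq2 and 5236, 7565, 2896 and 3188 with limma-voom. Without a low-count filter they were 5707, 7629, 2515 and 3249, and after subtracting the reads of the other organ 5203, 7555 and 3160 in liver, in lung and in both, with 5203 in liver also with the second choice of markers.

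Counts moved by over 1.5 times under stricter thresholds, by their construction. At an adjusted p under 0.01 they were 3158, 4977, 1391 and 1645, and with a log2 fold change of at least 1 in size 2320, 2366, 1576 and 809. With an estimated correlation camera called 0, 0 and 0 lists in liver, lung and their difference, against 10, 7 and 4 at an unadjusted p under 0.05 and 28, 33 and 7 by fry; the cause was not tested. Without a low-count filter 14 lists differed between organs, and the cause was not tested. Leaving out 1 library gave 3892 to 5056 genes in liver, 5891 to 8011 in lung, 2133 to 2956 in the difference and 2467 to 3291 in both organs. It gave 17 to 23 lists in liver, 24 to 30 in lung and 7 to 10 in the difference.

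With the replicate number as a block, 5245 genes were called in liver, 6870 in lung and 2968 in both organs, and 20 and 26 lists. For the difference between organs, the block by mouse gave 2901 genes and the block by number alone 2844 genes. The block by mouse gave 10 lists, 4 up and 6 down, against 5 up and 4 down without a block, so single list calls changed. The numbers were not taken to pair the libraries because the labels do not say that they do, a choice fixed before the data were examined. Correlations of deviations between liver and lung libraries of the same number were 0.193, 0.0935 and 0.264 in CLP and -0.0164, 0.0567 and 0.115 in sham. Each liver library correlated best with the lung library of its own number in all 3 CLP cases and in 2 of 3 sham cases. Sham replicate 1 did not, at -0.0164 against 0.0244 with lung sham replicate 2. CLP and sham libraries of the same number cannot share a mouse. In liver they correlated at 0.0172, 0.141 and 0.161, and in lung at -0.00285, 0.0444 and -0.00723. The correlations therefore do not show whether same-numbered libraries of liver and lung share a mouse. Depth limits genes with few counts, such as Il6, whose sham libraries held 2 counts in each organ.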

Other observations

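The tests that weigh the neutrophil pattern in this part were chosen after the result was seen. Of 29 genes of coagulation and fibrinolysis, 4 had a higher and 5 a lower response in lung than in liver (5 and 6 adjusted over the list alone), or 5 and 4 with library totals alone, and 3 had a lower one without liver sham replicate 3 or without a low-count filter. For the response of coagulation and fibrinolysis, camera gave an adjusted p of 0.794, and adjusted p = 0.920 with an estimated correlation. Thbd, thrombomodulin, which restrains clotting on endothelium, rose by 3.16 on the log2 scale in liver and fell by 0.94 in lung, a difference of -4.13 ± 0.46 (standard error). F3, tissue factor, which starts clotting, fell by 1.72 in liver and rose by 0.94 in lung (difference 2.62 ± 0.31). Both differences had adjusted p-values of at most 0.000141 in edgeR with Benjamini-Hochberg adjustment. Without liver CLP replicate 1, F3 lay at -2.31 in liver and its difference was 3.31. Of the list, 7 of 29 members rose and 3 fell in liver (7 and 3 adjusted over the list alone), or 6 and 9 with library totals alone, and 9 of 21 rose and 4 fell in lung (9 and 4 adjusted over the list alone). For coagulation and fibrinolysis in liver, camera gave an adjusted p of 0.334, and adjusted p = 0.836 with an estimated correlation. For coagulation and fibrinolysis in lung, camera gave an adjusted p of 0.0417, and adjusted p = 0.384 with an estimated correlation. The number that fell in lung was 2 without CLP replicate 1, CLP replicate 2 or sham replicate 1. The lung call ended without CLP replicate 2 (camera adjusted p = 0.102), sham replicate 2 (0.118) or sham replicate 3 (0.0837).

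Circadian clock genes fell in 8 of 20 cases in liver and rose in 3 (4 and 10 adjusted over the list alone), and in lung fell in 9 of 20 and rose in 3 (4 and 11 adjusted over the list alone). For circadian clock in liver, camera gave an adjusted p of 0.298, and adjusted p = 0.562 with an estimated correlation. For circadian clock in lung, camera gave an adjusted p of 0.430, and adjusted p = 0.871 with an estimated correlation. Without lung CLP replicate 3, 5 rose in lung. Tef, a transcription factor driven by the clock, fell by 1.41 on the log2 scale in liver and by 0.99 in lung (edgeR adjusted p = 0.0501 there without a low-count filter), and Nfil3, a repressor of the same targets, rose by 1.52 and 2.31. Erythroid markers in lung were lower for 5 of 8 and higher for 0 (0 and 6 adjusted over the list alone), and haemoglobin transcripts made up 0.144 ± 0.0339% of lung counts in sham and 0.0807 ± 0.0102% in CLP (SD, n = 3 each). For erythroid cells, camera gave an adjusted p of 0.0635, and adjusted p = 0.739 with an estimated correlation. Without CLP replicate 1, and also without CLP replicate 3, 3 were lower. The list was called without CLP replicate 2 (0.0339) and without sham replicate 2 (0.000963).

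Neutrophil precursor transcripts rose more than mature neutrophil transcripts in lung, with a median log2 fold change of 6.73 over 7 members against 2.34 over 16. The lowest CLP library exceeded the highest sham library by 1.77 in mean log2 CPM of precursor minus mature markers, which argues against more neutrophils of the makeup seen in sham. The smallest log2 fold change of the 2 precursor members with at least 100 sham counts was 4.57, above the largest of the mature markers, 3.74. This argues against folds inflated by low sham counts for these 2, Ngp and Ltf. The other members had at most 26 counts over the sham lung libraries. Their folds, and the median over 7 members, may still be inflated. Among them Prtn3 went from 26 to 162 counts in lung and Camp from 7 to 3076. Of 10 precursor members only 3 had at least 20 counts expected in CLP liver at their lung count per S100a8 count, Ngp, Ltf and Camp, and their counts there were 1.00, 0.759 and 0.793 times those expected, so that neutrophils of another maturity that reach both organs may account for the rise of these 3. The other 7, with at most 3.67 counts expected, cannot show an equal makeup, Prtn3 and Cebpe lay above it at 21 and 29 counts after 89 each in sham liver, and induction of these genes within neutrophils stays open and was not tested.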
